A study of Xenopus laevis with 30 samples.

How the data were processed

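The series holds 30 sequencing runs of total RNA from Xenopus laevis animal cap explants, which are lanes of 12 libraries: 4 groups of 3 libraries, with 3 lanes for each depleted and 2 lanes for each undepleted library. Groups and library numbers were taken from the run titles. For the NWS undepleted group the source names count only a pair of replicates and divide the lanes of library 2 between them, so the titles were followed. The labels' protocols speak of biological replicates, and p-values of single genes measure the spread between these libraries.

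Per the submitters' processing notes, bcl2fastq, STAR, featureCounts and DESeq2 were used upstream, with no versions. Genome build, annotation, strand setting and the treatment of reads that match several places are not given in the sources used here. The authors deposited, for each preparation, a table of raw counts per gene and library, with lanes already added up, and a table of FPKM values. The deposited FPKM values are scaled by median-of-ratios size factors of the same count table and not by the total count: the scale recovered from counts divided by FPKM differed from those factors by at most 0.00116%. All tests ran on the deposited counts, and the FPKM tables served only for that check. Each table has 49109 entries, most named with an L or S ending for the homeologs of this allotetraploid frog. Of these names 25709 are symbols of the reference gene table used here (assembly Xenopus_laevis_v10.1, names only, no coordinates), and 3698 LOC entries were given another symbol through their gene ID: sox5.L (LOC108710702), tfap2c.L (LOC108700915), znf608.S (LOC446274), batf.S (LOC108699837), arid4b.S (LOC108704885) and ccdc150.L (LOC108716943) are used in the text. Reads of homeologs and of multicopy genes such as histones may be split or lost between copies, so their levels are uncertain.

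Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the filterByExpr filter with a minimum count of 10, a quasi-likelihood fit per preparation with the group as the only term, and Benjamini-Hochberg adjusted p under 0.05. "Passed" and "called" refer to this threshold. CPM values are counts scaled to the TMM effective library size. The interaction of treatment and preparation was fitted on all 12 libraries, and the preparations were compared within NW. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a preparation, and again with the correlation estimated from the data and with fry. At the preset correlation members are set against other genes, and how they vary together between libraries is not taken from the data. Calls were also lost where the estimate was below 0.01, so a lost call need not mean that members vary together. Of 33 lists, 23 had the 5 tested members required in each preparation, but not the same 23. The preplacodal list was tested in the undepleted libraries only, and the replication-dependent histone list in the depleted ones only. DESeq2 1.42.0 and limma-voom were alternatives, DESeq2 with its default filtering. Single values were compared by exact two-sided permutation tests, which cannot go below p = 0.1 for 3 against 3. Figures used Python 3.11.15 with matplotlib 3.10.9.

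Whether library numbers pair the libraries was read from the data. Deviations from the group means of NW and NWS libraries with the same number correlated at 0.139, 0.248 and 0.155 (depleted) and 0.210, 0.244 and 0.131 (undepleted), each above 0.1 and above every correlation with another number. The numbers were therefore taken to pair the libraries, which the labels do not say, and fits with the replicate block are printed where they change a call. These correlations are low, and shared library quality cannot be told apart from a shared origin. The highest were at number 2, whose NW and NWS libraries had most counts in LOC108705792 and ccdc50.L (86.0% and 88.3% depleted, 95.2% and 95.1% undepleted). Deviations from a group mean also cancel out over its libraries, which pushes correlations with other numbers down.

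Alternatives covered size factors, upper-quartile scaling, low-count filters, tools, the replicate block, a fit of all 12 libraries, homeologs summed, entries left out, thresholds and each library left out. The gene lists, the tests and these alternatives were fixed before the data were examined. Added afterwards were fits without both libraries numbered 2, without the 5 dominant entries (over 0.5% of the counts of any library), with DESeq2's filtering tuned to 0.05 and with both preparations summed. Most alternatives of the list tests and some of the interaction, of the comparison of preparations and of their correlation were also added then. The number of thinnings in the depth test was raised from 20 to 100 after the first draws were seen. Named entries followed a rule: sf3b4, nog and wnt8a; in each preparation up to 8 higher and 8 lower entries that passed without overlap, at a mean CPM of at least 5 and with a gene symbol, and likewise up to 5 each way for the comparison of preparations; and for each list up to 4 members that passed, or else the 2 with the highest mean CPM. Other names were chosen after their values were seen. No column of values per sample was left unused.

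The fits were tested on simulated counts drawn from the real means and library sizes with 200 genes changed, 50 at each size. In the unblocked fit of the depleted libraries (5559 genes) 0% of the 2-fold, 4% of the 4-fold, 18% of the 8-fold and 52% of the 16-fold changes were recovered. The undepleted fit (5273 genes) recovered 0%, 6%, 18% and 58%. The blocked fits recovered 44% (5477 genes) and 30% (5104 genes) of the 16-fold changes. For these, a random effect of the library number was added to a spread taken from the unblocked fit. The shares may therefore be too low for the real blocked fits. The interaction fit (10715 genes) recovered 6% and the comparison of preparations (9146 genes) 34% of them. Changes of 8-fold or less in a single gene were thus mostly missed at the simulated depth and spread.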

Results

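RNA was sequenced from animal caps of the frog Xenopus laevis, the pluripotent ectoderm that can be cut from a blastula and grown in a dish. All embryos had received mRNA for noggin, an antagonist of BMP signalling, and for the ligand wnt8, a pairing used to turn ectoderm into neural crest progenitors. The control explants are called NW here. The other explants, called NWS, came from embryos that had also received a morpholino against Sf3b4, a subunit of the SF3b complex of the U2 small nuclear ribonucleoprotein, which takes part in splicing. Injection was at the 2-cell stage, the caps were dissected at stage 8 to 9, and RNA was taken after 8 hours of culture. Libraries were made with removal of ribosomal RNA (depleted) or without it (undepleted), giving 4 groups of 3 libraries, which the labels call biological replicates. The comparison named by the series is NWS against NW.

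Few of the counts in most libraries came from genes other than a pair of entries. LOC108705792 and ccdc50.L together held 19.3% to 88.3% of the counts in the depleted libraries and 48.8% to 95.2% in the undepleted libraries. Total counts ran from 351902 to 3570364 in the depleted and from 3499960 to 4339788 in the undepleted libraries. Outside the 5 dominant entries, each above 0.5% of the counts of some library, 112762 to 2803732 counts were left in the depleted libraries and 87172 to 2042925 in the undepleted ones. NW library 3 was the deepest of its group in both preparations by this measure, and NW library 2 the shallowest. A floor of 3 counts corresponded to 0.268 to 7.58 counts scaled to library size (CPM) in the depleted and 0.110 to 2.76 CPM in the undepleted libraries, a limit that covers counting error only.

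**Figure D1:**
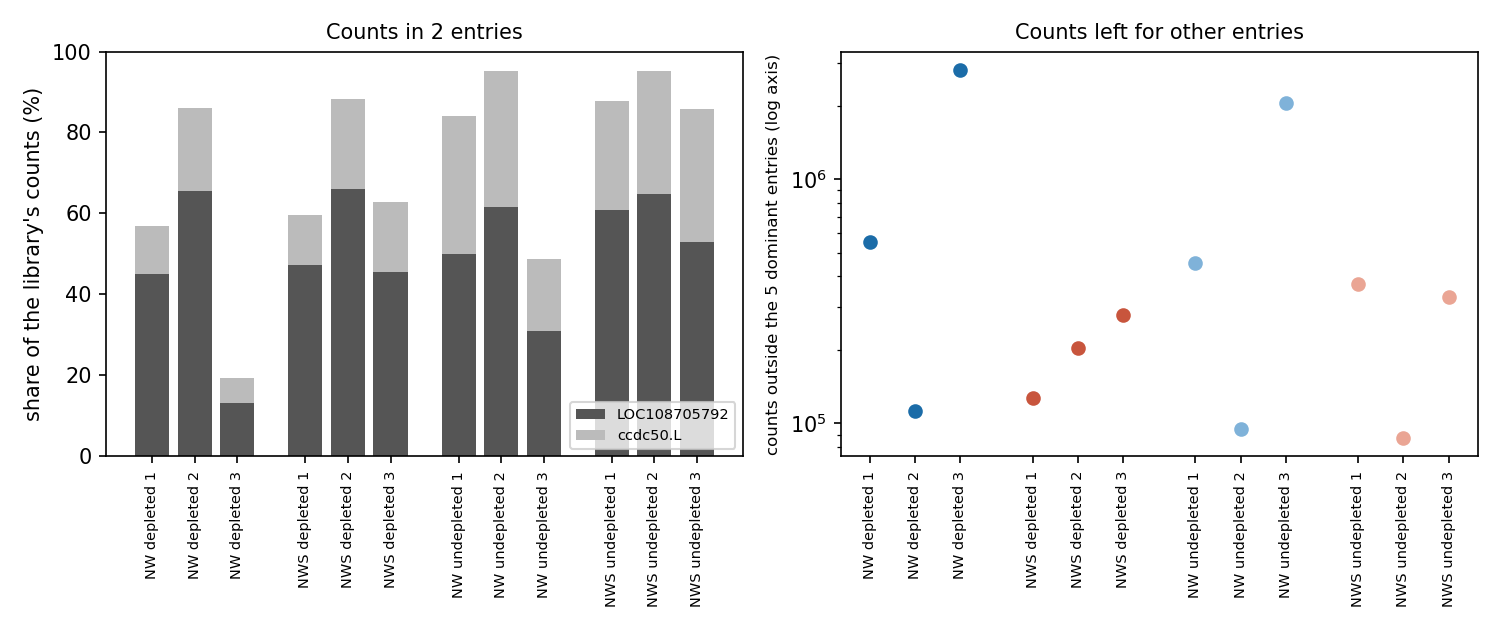
Share of each library's counts in LOC108705792 and ccdc50.L (left, stacked bars, percent) and the number of counts outside the 5 dominant entries (right, log axis), for the 12 libraries. The counts left for other genes range from 87172 to 2803732, and NW library 3 has the most in both preparations.

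The targeted transcript did not pass the test in either preparation. With depletion, sf3b4.L stood at 19.1 ± 7.32 CPM in NW and 20.4 ± 14.6 CPM in NWS (SD, n = 3 each), and sf3b4.S at 17.9 ± 2.92 and 10.1 ± 5.58 CPM. Without depletion, sf3b4.L stood at 6.73 ± 3.24 and 8.02 ± 3.93 CPM, and sf3b4.S at 7.54 ± 4.17 and 6.69 ± 2.65 CPM. The log2 fold changes were 0.10 ± 0.97 (SE) and -0.87 ± 1.03 in the depleted libraries and 0.34 ± 0.81 and -0.13 ± 0.83 in the undepleted libraries, with edgeR adjusted p of 0.999 in the depleted and 1.00 in the undepleted fits. The kind of morpholino is not given in the sources used here, and one that blocks translation need not change the mRNA, so these values do not check the knockdown. Whether the nog and wnt8a entries count the injected messages is not known here. Among them, nog.L gave log2 fold changes of 2.24 ± 1.11 and 1.99 ± 0.91 in the depleted and undepleted libraries (edgeR adjusted p = 0.999 and 1.00). It had no counts in NW library 2 of either preparation, although all embryos had received the mRNA. The entry wnt8a.L was higher in every NWS library than in every NW library of both preparations, at 1.66 ± 1.05 against 13.8 ± 15.2 CPM (depleted) and 0.196 ± 0.340 against 4.79 ± 3.13 CPM (undepleted). The exact two-sided permutation test gave p = 0.1 in each preparation, the smallest value that 3 against 3 libraries allow. The wnt8a.L levels rest on 0 to 34 counts per library, with 0 in undepleted NW libraries 1 and 2. The depleted NWS libraries 1 and 2 and undepleted NWS library 2 had 3 counts each, so their order against NW may be counting error. The entries nog.S and wnt8a.S had at most 41 and 6 counts in any library.

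When libraries of the same number were paired, 13 entries of the depleted libraries passed, 5 higher and 8 lower in NWS, and none passed without the pairing. Both copies of id3, a helix-loop-helix inhibitor that responds to BMP and is expressed in crest progenitors, were among the lower ones. The mean level of nog.L, which codes for a BMP antagonist, was higher in NWS as given above, and any link to id3 was not tested. id3.L went from 190 ± 57.7 CPM to 40.1 ± 30.8 CPM (n = 3, blocked log2 fold change -2.59, edgeR adjusted p = 0.0386) and id3.S from 197 ± 150 to 24.4 ± 13.1 CPM (-2.84, edgeR adjusted p = 0.0106). The other lower entries were sox5.L, a SoxD transcription factor gene with a place in the crest list, the calcium channel gene ryr3.L, the DNA polymerase zeta gene rev3l.L, caprin2.S and the unnamed entries Xelaev18022166m and Xelaev18022167m. The higher entries were phldb3.S, lmo7.L, znf608.S, LOC108719216 and batf.S, the last with no counts in any NW library and carried by NWS library 2 (37.3 CPM, against 7.85 and 7.37 CPM in the other NWS libraries). With both preparations of a library summed, the paired fit kept 8 of the 13 calls and lost sox5.L, ryr3.L, rev3l.L, znf608.S and batf.S. The sum holds the depleted counts that gave the calls, so the kept ones are no independent repeat. Without the pairing, 0 of 6585 entries passed edgeR's quasi-likelihood test at an adjusted p under 0.05, with 245 at an unadjusted p under 0.05 where chance gives 329, and DESeq2 called 9 entries and limma-voom 2. The unblocked count was 24 without NWS library 1, 7 without NW library 1, 4 without NWS library 2 and 3 without NWS library 3. Spread between libraries was wide, with a biological coefficient of variation of 0.743, and 8.64% of the entries had groups that did not overlap, where chance gives 10%.

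In the undepleted libraries, 1 of 6284 entries passed without pairing and 14 with it, 7 higher and 7 lower in NWS. The entry that passed in both fits was Xelaev18022166m, which has no name in the table used here. It fell from 194 ± 55.3 CPM in NW to 10.8 ± 3.96 CPM in NWS, a log2 fold change of -4.14 ± 0.66 (edgeR adjusted p = 0.0112). Depleted libraries had the same entry at 387 ± 86.5 and 33.1 ± 12.6 CPM, with -3.55 ± 0.68 and an edgeR adjusted p of 0.119 without and 5.82e-06 with the pairing. With the pairing, id3.L (63.8 ± 40.9 to 10.8 ± 6.29 CPM, log2 fold change -2.54, edgeR adjusted p = 0.0167) and the crest regulator sox10.S (34.1 ± 29.2 to 4.36 ± 7.56 CPM, -4.16, edgeR adjusted p = 0.0126) were lower, as were the focal adhesion gene tns1.L, arid4b.S and Xelaev18022167m. The nuclear receptor corepressor gene nrip1.L had no counts in any NWS library. Its NW mean was 5.49-fold the mean floor of 3 counts in NWS, which leaves out the spread between libraries. Higher entries were the tight junction gene cldn4.L (2.45 ± 3.31 to 24.9 ± 22.4 CPM, log2 fold change 3.73, edgeR adjusted p = 0.0167), the ligand gene wnt7c.L, the cofactor gene vgll3.L, the phosphatase gene dusp5.L, the histone gene hist2h3c.L, phldb3.S and LOC108711332. The paired fit of summed preparations, which holds the same undepleted counts again, kept 12 of the 14 calls and lost wnt7c.L and hist2h3c.L. Without pairing, 253 entries had an unadjusted p under 0.05 where chance gives 314, and DESeq2 called 19 entries and limma-voom 1. The call of Xelaev18022166m was lost without NWS library 2 (edgeR adjusted p = 0.0586), without both libraries numbered 2 (edgeR adjusted p = 0.162) and with both preparations of a library summed (edgeR adjusted p = 0.0623). Its log2 fold change in these fits was -3.82, -3.88 and -3.83. The number of calls was 26 without NW library 1, 25 without NWS library 1, 6 without NWS library 2, and 3 without NW library 2 or NWS library 3.

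Of the entries that passed with the pairing, 4 did so in both preparations, with the same direction in each: id3.L, Xelaev18022166m and Xelaev18022167m were lower and phldb3.S was higher. Libraries of a number may share their RNA, so this is no independent repeat. In the undepleted libraries phldb3.S was at 0.183, 0.920 and 0.737 CPM in NW and 1.01, 13.7 and 29.9 CPM in NWS. The change there rested on NWS libraries 2 and 3. The undepleted vgll3.L was at 2.21 CPM in NW library 3 and 2.22 CPM in NWS library 1. All entries named in the last 3 paragraphs other than sf3b4, nog, wnt8a, id3 and hist2h3c.L were picked after their values had been seen.

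**Figure D2:**
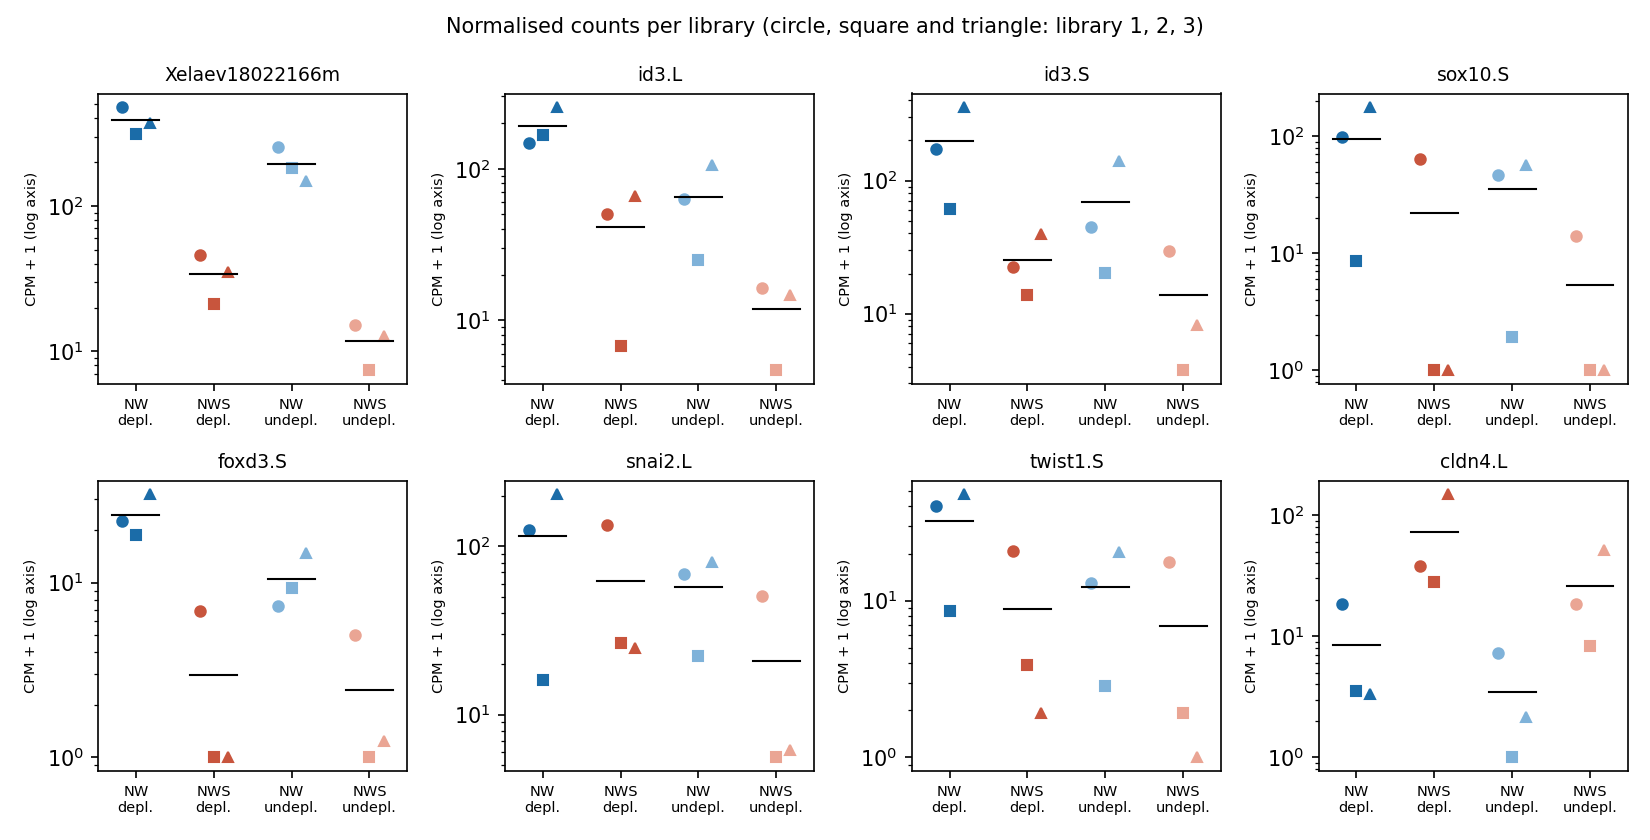
Normalised counts (CPM + 1, log axis) per library for 8 entries in the 4 groups, with each group's mean as a bar and library numbers as symbols. The NW libraries of Xelaev18022166m lie above all NWS libraries in both preparations, while sox10.S reaches 63 or less in every NWS library and overlaps NW library 2.

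Most genes of the neural crest specifier list were lower in NWS, though the libraries within a group differed by more than the groups did. Of the 30 members tested in the depleted libraries 25 were lower and 5 higher, with a median log2 fold change of -1.01, and of the 29 in the undepleted libraries 25 were lower and 4 higher, with a median of -1.01. The transcription factor genes sox10.S, foxd3.S and sox8.S gave -2.27 ± 1.17, -3.87 ± 1.38 and -2.49 ± 1.08 in the depleted libraries (edgeR adjusted p of 0.999, 0.932 and 0.999), picked after their values were seen. The complement gene c3.L, by contrast, gave 0.88 ± 0.66 and 1.12 ± 0.63 in the depleted and undepleted libraries, and tfap2c.L -0.39 ± 0.65 and -0.21 ± 0.65. No member passed over all genes without pairing, and 1 did in each preparation when adjusted over the list alone. With pairing, 3 passed in the depleted and 2 in the undepleted libraries over all genes, and 11 and 15 when adjusted over the list alone. The list test (camera from limma, preset correlation) gave adjusted p = 1.84e-09 in the depleted and 7.43e-08 in the undepleted libraries, and adjusted p = 0.593 and 0.848 with an estimated correlation. The estimated correlation of its members was 0.471 (depleted) and 0.564 (undepleted).

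The summed level of the crest list spanned 1447 to 3988 CPM over the NW and 1285 to 2582 CPM over the NWS depleted libraries, and 322 to 1321 and 365 to 847 CPM over the undepleted ones. The exact two-sided permutation test of that level gave p = 0.5 in the depleted and p = 0.7 in the undepleted libraries, with 3 libraries per group. By library number the sum was lower in NWS in 1 of 3 pairs of each preparation (log2 differences of 0.06, 0.04 and -1.63 depleted, 0.16, 0.18 and -1.71 undepleted). It leans on c3.L, which moved against most of the members and made up 37.8% and 38.0% of it in NWS. Without c3.L, left out after its direction was seen, it was 2273 ± 991 CPM in NW and 1112 ± 712 CPM in NWS (depleted) and 707 ± 430 and 334 ± 284 CPM (undepleted), with pair differences of -0.19, -0.78 and -2.37 (depleted) and -0.07, -0.98 and -2.54 (undepleted) and exact permutation p = 0.2 in each. A regrouping of NW libraries 1 and 3 with NWS library 1 against the other 3 moved the list by more than the real groups, with medians of -1.95 and -2.15 (camera adjusted p = 1.85e-18 and 8.32e-22, limma). It keeps both libraries numbered 1 together and both numbered 2 together, so it also holds any difference between numbers. Without NWS library 1 the median was -2.72 (depleted) and -2.94 (undepleted), and without NW library 3 it was -0.56 and -0.57. It was -0.66 without NWS library 2 in the depleted libraries and -0.59 without NWS library 3 in the undepleted ones. With pairing it was -1.61 and -1.68. The other splits that part all pairs, fitted with pairing, gave medians of 0.65, -0.77 and 1.33 (depleted) and 0.82, -0.62 and 1.41 (undepleted).

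**Figure D3:**
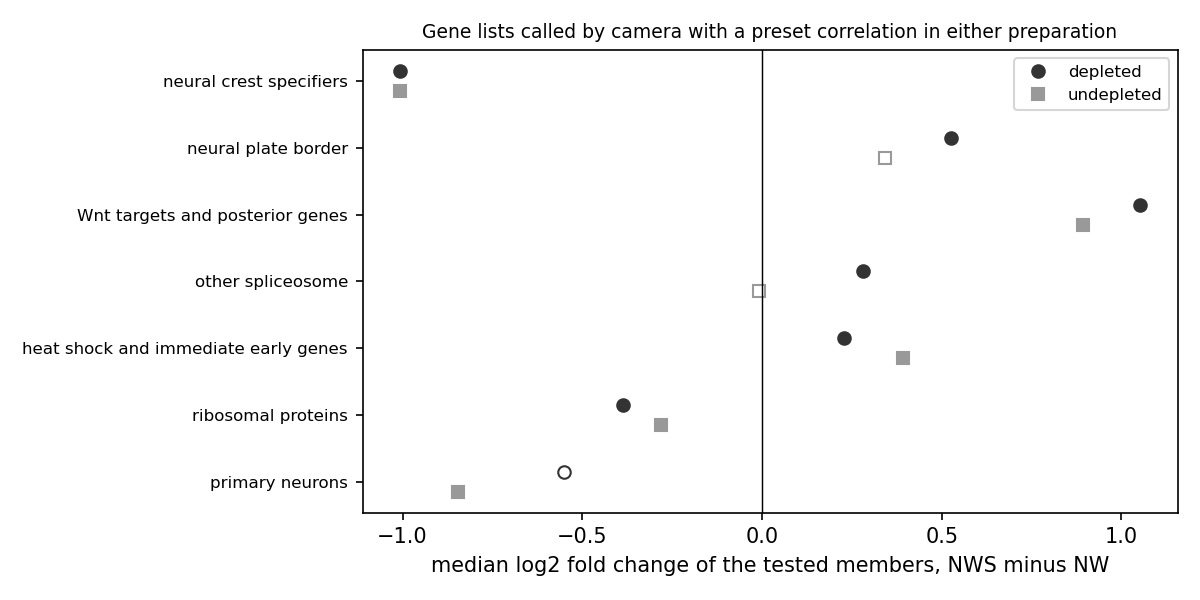
Median log2 fold change (NWS minus NW) of the tested members of each gene list that passed camera's test with a preset correlation in either preparation. Filled symbols passed in that preparation, the crest list lying at -1.01 in both and the Wnt list at 1.05 and 0.89, and no list passed with an estimated correlation.

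Wnt target and posterior genes were higher in NWS as a list, which holds no Hox genes. In the depleted libraries 16 of 19 tested members were higher, with a median log2 fold change of 1.05, and in the undepleted libraries 15 of 20, with a median of 0.89. The Wnt receptor gene fzd7.L gave 1.55 ± 0.84 and 1.57 ± 0.77, and the homeobox gene meis3.S 1.32 ± 0.70 and 0.79 ± 0.71. The Wnt-responsive gene sp5.L, picked after its values were seen, gave 3.92 ± 1.16 in the undepleted libraries (edgeR adjusted p = 0.601) and had too few counts to be tested in the depleted ones. No member passed over all genes with or without pairing, and when adjusted over the list alone 0 and 1 passed without it and 1 and 2 with it. Camera from limma gave adjusted p = 5.29e-04 and 8.09e-04, and adjusted p = 0.263 and 0.601 with an estimated correlation. The undepleted call was lost without NW library 1 (limma adjusted p = 0.383). The depleted median was 0.69 without both libraries numbered 2, and the undepleted median was 0.54 without a filter on low counts. The higher wnt8a.L level given above moved with this list. A separate Hox list had 2 tested members in each preparation, too few for a test, and its summed level went the other way. That sum was 184 ± 111 CPM in NW and 67.4 ± 29.6 CPM in NWS (depleted), and 52.0 ± 40.9 and 22.4 ± 9.67 CPM (undepleted), with overlapping libraries. In it, hoxc3.S had no counts in any NWS library. Its NW mean was 3.15-fold (depleted) and 5.33-fold (undepleted) the mean floor of 3 counts in NWS, which leaves out the spread between libraries. The undepleted NW libraries stood at 3.65, 17.5 and 0.663 CPM, so library 2 carried that mean. The member hoxb1.S (LOC108702519) gave 0.08 ± 0.94 and 1.13 ± 0.92.

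Heat shock and immediate early genes were also higher in NWS as a list in both preparations. Of the tested members 15 of 24 were higher in the depleted libraries (median log2 fold change 0.23, limma adjusted p = 0.0230) and 18 of 26 in the undepleted ones (0.39, limma adjusted p = 0.00449), with adjusted p = 0.593 and 0.601 with an estimated correlation. The members with an unadjusted p under 0.05 in both included the chaperone genes hsp90aa1.1.L and hsph1.S and the MAP kinase phosphatase gene dusp5.L, at log2 fold changes of 3.58 ± 1.24, 1.73 ± 0.78 and 2.39 ± 0.90 in the undepleted libraries, and were picked after their values were seen. The abundant chaperone genes hsp90ab1.S and hspa8.S gave 0.41 ± 0.63 and 0.40 ± 0.64 in the depleted libraries. Without pairing no member passed in the main edgeR fit, over all genes or when adjusted over the list alone. This depended on tool and filter: unpaired DESeq2 called nr4a1 in both preparations and fos.S and egr1.S in the undepleted libraries. Unpaired edgeR with no low-count filter called nr4a1 and jun.L in both. With pairing dusp5.L passed over all genes in the undepleted libraries (edgeR adjusted p = 0.0305), and 3 and 1 members passed when adjusted over the list alone. The depleted call was lost without NWS library 3 (limma adjusted p = 0.248), and both calls were lost with the dominant entries left out (limma adjusted p = 0.211 and 0.0596). The median moved to 0.95 and 1.53 without NW library 3.

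Ribosomal protein genes were lower in NWS as a list, by a small amount. In the depleted libraries 94 of 125 were lower (median -0.39, limma adjusted p = 0.00294) and in the undepleted libraries 93 of 124 (-0.28, limma adjusted p = 0.0147), with adjusted p = 0.708 and 0.913 with an estimated correlation. The gene rps12.L gave -1.31 ± 0.80 and -1.51 ± 0.74. No member passed, over all genes or when adjusted over the list alone. Without NWS library 2 the depleted call was lost (limma adjusted p = 0.991) and the undepleted list turned to higher (median 0.13, limma adjusted p = 0.772). Both calls were also lost without NW library 1 (limma adjusted p = 0.368 and 0.168) and without NW library 3 (0.177 and 0.693). The undepleted call was lost without NWS library 3 (0.0902) and without both libraries numbered 2 (limma adjusted p = 0.238) as well. Without NW library 2 the medians were -0.71 and -0.48, and without NWS library 1 they were -0.62 and -0.53.

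The neural plate border and non-SF3 spliceosome lists were higher in the depleted libraries and the primary neuron list lower in the undepleted ones, with no member passing over all genes or over the list alone without pairing; with it, 1 border member passed over the list alone. For the border list 14 of 18 members were higher (median 0.53, limma adjusted p = 0.0230, adjusted p = 0.593 with an estimated correlation), among them msx2.L at 0.83 ± 0.68. That call was lost without NW library 1 (limma adjusted p = 0.529), without NWS library 2 (0.0520) and with the dominant entries left out (0.0741). For the spliceosome list 40 of 65 members were higher, with a median of 0.28 and snrnp70.L at 0.28 ± 0.73. The list gave limma adjusted p = 0.0395, and adjusted p = 0.572 with an estimated correlation of 0.00617, below the preset 0.01. That call was lost without NW library 1 (limma adjusted p = 0.594), NW library 3 (0.0767) or NWS library 2 (0.0709) and without the dominant entries (0.146). For the neuron list 8 of 10 members were lower (median -0.84, limma adjusted p = 0.0340, adjusted p = 0.601 with an estimated correlation), with myt1.L at -1.26 ± 0.76. Of the 6 fits that left out a library, only the one without NW library 1 kept that call (limma adjusted p = 7.68e-04), and the others gave 0.0578 to 0.887. It was also lost with homeologs summed (limma adjusted p = 0.170), without both libraries numbered 2 (0.446) and without the low-count filter (0.821). The same lists in the other preparation gave limma adjusted p of 0.121 (border), 0.384 (spliceosome) and 0.371 (neurons), and the difference between preparations was not tested for lists. The SF3 and U2 snRNP list, which holds the partners of Sf3b4, had medians of 0.16 over 35 and -0.12 over 37 members (limma adjusted p = 0.853 and 0.861).

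The effects in the depleted and undepleted libraries went together across entries. Over 5326 entries tested in both, the log2 fold changes had Pearson r = 0.456 and Spearman rho = 0.412 across entries, which are not independent replicates, and 64.4% had the same sign. Of the 10 splits of the libraries 6, the real one among them, gave an r at least as high. The entries cldn4.L (3.19 ± 0.95 and 3.21 ± 0.92) and id3.S (-3.01 ± 0.75 and -2.35 ± 0.79) are examples. The libraries of a number in both preparations correlated best with each other in all 6 cases, so this is not a repeat on independent explants. Asked whether the effect differed between preparations, edgeR's interaction test called 0 of 13224 entries (smallest adjusted p = 1.00), with 231 at an unadjusted p under 0.05 where chance gives 661, and DESeq2 also called 0. Leaving out a library gave up to 8 calls (without NW undepleted library 1), 6 without NW depleted library 1, 3 without NWS undepleted library 1, 2 without NWS depleted library 3, and 1 without NWS depleted library 1 or NW undepleted library 3.

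**Figure D4:**
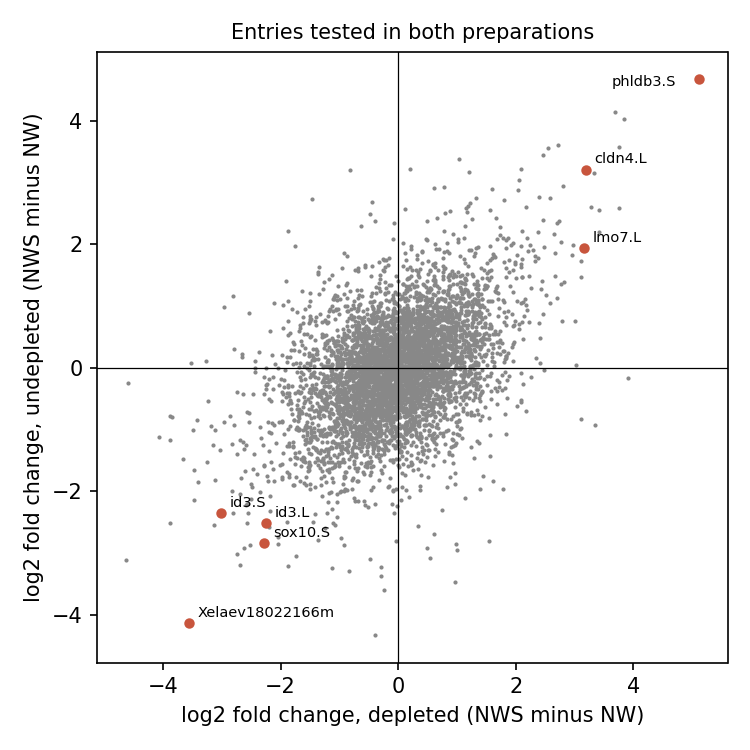
Log2 fold change (NWS minus NW) in the depleted (x axis) and undepleted (y axis) libraries for the 5326 entries tested in both, each a grey point, with 7 entries named in red. Pearson r across entries is 0.456.

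Between preparations of the NW explants, 4 of 10633 entries passed without pairing, all lower in the depleted libraries. They were Xelaev18016727m (log2 fold change -7.88 ± 1.02, edgeR adjusted p = 3.58e-07), Xelaev18003021m (-5.06 ± 0.90, edgeR adjusted p = 0.00131), trim45.L (-5.39 ± 1.16, edgeR adjusted p = 0.0340) and Xelaev18034099m, which had no counts in the depleted libraries against 26.8 ± 30.2 CPM in the undepleted ones (n = 3, edgeR adjusted p = 0.00263). With libraries of a number paired, 11 passed, 10 of them lower, while trim45.L did not (edgeR adjusted p = 0.0848); among the lower were ccdc50.L (-2.82 ± 0.10, edgeR adjusted p = 4.97e-167) and LOC108705792 (-1.99 ± 0.09, edgeR adjusted p = 9.04e-105). The one higher entry was ccdc150.L, at 10.4 ± 0.699 CPM undepleted and 76.5 ± 79.2 CPM depleted. These entries were named after their values were seen. Of them, trim45.L was at 76.7 ± 130 CPM undepleted and 2.15 ± 1.55 CPM depleted, with overlapping libraries. The preparations were also sequenced in different lanes, so removal of ribosomal RNA and lane cannot be told apart. At an unadjusted p under 0.05 there were 141 entries where chance gives 532. Without both libraries numbered 2 the unblocked count was 0, and it was 1 without NW library 2 of either preparation, 9 without NW library 1 of either preparation and 7 without NW undepleted library 3.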

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

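No result met the rules for a closer look set in advance: groups of 3 are too small for the test of a library apart from the others, 0 of 84 named entries moved in opposite directions in the preparations without overlap, and no entry passed the interaction test. Of the tests below, those on variation between explants, on the crest list in paired splits, on wnt8a and on the 2 dominant entries were chosen after the result was seen. Chance was weighed by regrouping the libraries: 3 against 3 libraries make 10 splits and 4 that part all pairs, too few for a share under 0.05.

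The crest list was lower in NWS in both preparations. A difference in depth was tested by thinning all libraries of a preparation to the same number of counts outside the dominant entries (112762 and 87172). Over 100 thinnings the list's median shrank from -1.01 to -0.72 ± 0.16 (SD over thinnings, depleted) and from -1.01 to -0.76 ± 0.22 (undepleted). The thinned fits also left out the dominant entries and filtered no further, so the shrinkage cannot be put down to depth alone. The median was still below the bound of -0.5 set beforehand, which argues against the number of counts as the whole cause. Both margins are narrow, and the number of thinnings was raised from 20 after a pair of smaller draws had fallen on both sides of the depleted criterion. Crest induction that varies between explants of a group remains a candidate explanation: the summed list level ranged over 1.46 (depleted) and 2.04 (undepleted) on the log2 scale within a group, against group differences of -0.51 and -0.46, and without c3.L, which leads the sum and was left out because it moved the other way, over 1.60 and 2.2 against -1.11 and -1.20. These ranges ignore the pairing. By pairs the level was lower in NWS in 1 of 3 with all members and in 3 of 3 without c3.L, in each preparation. Of the 10 unpaired splits 3 gave the list a p as small as the real one in each preparation (-log10 p of 10.1 and 8.49, with 19.1 and 22.4 as the highest of the others), and with the block 2 of the 4 splits that part all pairs did (limma adjusted p = 2.19e-12 and 6.78e-11, with limma adjusted p = 1.66e-12 and 2.12e-12 as the lowest of the others). An effect of the morpholino stays open beside it: with the block the median was -1.61 and -1.68. In size that was the largest of the 4 splits in each preparation, the others reaching at most 1.33 and 1.41, but 4 splits are too few to judge chance.

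The Wnt target list was higher in NWS. More wnt8a RNA in the NWS libraries could account for it: wnt8a.L was higher in every NWS library, by 4.59 CPM on average in the undepleted libraries, with exact p = 0.1 in each. That order rests on 3 counts in depleted NWS libraries 1 and 2 and in undepleted NWS library 2. Whether the level goes with the group in every library is therefore uncertain. The morpholino and the amount of wnt8a message cannot be told apart here.

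The pair of entries with most of the counts, LOC108705792 and ccdc50.L, may hold reads of ribosomal RNA that the depletion removed in part. Per count outside the dominant entries, both were lower after depletion in 6 of 6 pairs of libraries, by at least 3.38-fold. Messenger RNA of ccdc50.L is argued against, since the depletion should leave it in place and the blocked log2 change was -2.82 ± 0.10 (SE). Its homeolog ccdc50.S had at most 11 counts in any library where ccdc50.L had at least 43105. No biological explanation was tested.

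For the counts of genes, the depleted libraries gave 0 calls and another split 4 (10 of 10 splits as many as the real one, as a count of 0 must give), and the undepleted libraries 1 against at most 5 (3 of 10). With the block the real split gave 13 and 14 calls and the other splits that part all pairs at most 3 and 2 (1 of 4 in each, the real one). The list tests gave 6 calls against at most 6 (3 of 10, depleted) and 5 against at most 9 (4 of 10, undepleted). The correlation between preparations was 0.456 against at most 0.549 (6 of 10). Between preparations in NW the real split gave 4 calls and another split 36 (5 of 10 splits as many); these splits ignore that both preparations of a number go together, and paired splits were not run. For the interaction 50 of 50 drawn splits gave at least the real 0 calls, which was bound to be so and says nothing about chance, and a drawn split gave 221.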

How the results depend on the processing

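Few of the gene counts were stable. The fits without both libraries numbered 2, with tuned DESeq2 filtering, with summed preparations and most list alternatives were chosen after seeing the data. In the depleted libraries the 0 calls became 20 with no low-count filter (9 higher), 16 with a CPM of at least 1 in 3 libraries, 9 with DESeq2 (15 with tuned filtering), 2 with limma-voom, 3 with all 12 libraries in 1 fit, 13 with the replicate block, 1 without both libraries numbered 2, and 26 with both preparations summed and the block; leaving out a library gave 0 to 24. In the undepleted libraries the 1 call became 29, 15, 19 (19 tuned), 14 with the replicate block, 0 summed, 26 summed with the block, and 0 at an adjusted p under 0.01; leaving out a library gave 1 to 26. Looser filters tested more genes, but some of their added calls were of entries that the main fit had tested as well. An example is Xelaev18022166m in the depleted libraries, with an edgeR adjusted p of 0.119 in the main fit and 0.00439 with no filter. The cause of the changed counts was not tested. The interaction count of 0 held with another scaling, filter, tool and block, and went from 0 to 8 with a library left out. Between preparations in NW the 4 calls became 9 without the filter, 11 with the replicate block and 0 without both libraries numbered 2; leaving out a library gave 1 to 9.

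The 11 list calls became 0 with an estimated correlation, 0 with fry and 22 without the filter; leaving out a library gave 9 to 18. For the crest list the adjusted p was 0.593 and 0.848 with an estimated correlation and 0.615 and 0.831 with fry (depleted, undepleted); for the Wnt list it was 0.263 and 0.601, and 0.315 and 0.658. With a library left out the undepleted Wnt list ranged from 3.82e-07 to 0.383 (limma). The ribosomal protein list reversed in the undepleted libraries without NWS library 2 (adjusted p = 0.772, with a range over left-out libraries of 7.45e-05 to 0.772). The correlation between preparations was 0.534 at a mean CPM of at least 5 and 0.411 to 0.509 without a library number. The block ended no list call that the text gives. Of 3021 NWS against NW values of named entries under an alternative, 2873 stayed on the same side of the threshold, 145 were called under the alternative only, 3 lost their call, and 157 had the other sign, none of them called. That tally leaves out the comparison of preparations, where calls were lost as given above. Taking the first lane alone was not run, since lanes had been added up before deposit.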

Other observations

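Of the replication-dependent histone list 5 entries were tested in the depleted libraries, with a median log2 fold change of 1.47 and a limma adjusted p of 0.0706 (adjusted p = 0.708 with an estimated correlation), so the list did not pass; it did with the replicate block (limma adjusted p = 0.0425, and adjusted p = 0.618 with an estimated correlation). Of the 5, 3 were higher. Too few members were tested for a list test in the undepleted libraries. The entry hist2h3c.L gave 1.74 ± 0.67 in the depleted and 2.16 ± 0.71 in the undepleted libraries, while hist2h3d.L gave -0.74 ± 0.61 in the undepleted ones. Cell cycle genes did not pass (limma adjusted p = 0.456 and 0.121, medians 0.10 and 0.20), with mki67.L at 0.43 ± 0.60 and 0.87 ± 0.58.

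Epidermal genes did not pass as a list (medians 0.03 and 0.40, limma adjusted p = 0.312 and 0.171), but did without both libraries numbered 2 (medians 1.41 and 0.30, limma adjusted p = 0.00150 and 0.00231). With all libraries the list had adjusted p = 0.708 and 0.848 with an estimated correlation, which was not run for the smaller fit. Of the members, 2 and 3 passed when adjusted over the list alone, all higher. They were cldn4.L and epcam.S in the depleted libraries and cldn4.L, epcam.L and upk1b.S in the undepleted ones, named after their values were seen, while krt12.S gave -1.29 ± 1.13 in the depleted libraries. In p53 pathway genes the median was 0.76 in the depleted and 0.18 in the undepleted libraries (limma adjusted p = 0.0858 and 0.947), and without both libraries numbered 2 the list passed in the depleted ones (limma adjusted p = 9.09e-04). With all libraries that list had adjusted p = 0.708 and 0.979 with an estimated correlation. The polo-like kinase gene plk2.L gave 3.85 ± 1.11 and 4.03 ± 1.19 and rested mostly on NWS library 3, at 252 of a group mean of 92.4 CPM in the depleted libraries. Splicing regulators had medians of 0.04 and -0.04 (limma adjusted p = 0.943 and 0.861), and factors of nonsense-mediated decay -0.17 and -0.13 (0.602 and 0.897).

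Endoderm and blood markers had few counts. The endoderm list summed to 85 counts over the NW and 30 over the NWS depleted libraries, which differ in depth, the blood and endothelium list to 244 and 42, and none of their members passed the filter. The mitochondrially encoded list had 13 entries and no counts in any library.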
